A study of Mus musculus with 8 samples.

How the data were processed

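RNA was measured in kidneys of C57/BL6 mice carrying haplotype II (Hap-II) of the human angiotensin receptor type 1 gene, all on a western diet. Per the labels, 4 animals were adult and 4 were aged, and each gave 1 library. RNA was extracted with a Qiagen kit, and stranded libraries were made after pull-down of polyadenylated RNA, per the labels' protocols. The series' design text states 4 animals per group, so the replicates are separate animals.

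The deposited values are TPM, a length-normalized relative abundance scaled to a fixed total, in 1 table of 30153 mouse gene identifiers and 8 libraries. The submitters' processing notes name kallisto, DESeq2 and the mouse build GRCm38, without versions, roles or order. Which step made the TPM, and the annotation used for it, are not given in the sources used here. The 8 columns totalled between 924798 and 950974 TPM. TPM keeps no read depth, so the depth of each library is unknown and no counting interval was computed. The human transgene has no row in a table of mouse genes, and its level was not analysed here. Shares of the TPM scale are in percent of its nominal fixed total, which the column totals do not quite reach. All columns were matched to samples by name.

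Identifiers were matched to gene symbols in a reference table, with 29732 of 30153 (98.6%) matched, and 7 identifiers that shared a symbol with another were summed with it. All libraries had 0 for 9798 rows. Values identical to another row in every library occurred in 244 rows, of which 78 were tested. Coordinates, transcript lengths and biotypes came from GENCODE release M21 on GRCm38, the build that the notes name. A gene's transcript length was the median over its annotated transcripts, which need not be the length of the transcript measured. It was found for 11734 of the 11796 genes tested (99.5%). Nuclear copies of mitochondrial transcripts were defined as genes of which at least 0.5 of the 31-base words occurred in a mitochondrial transcript. Genes with near-identical copies, processed pseudogenes among them, can trade reads with those copies, so their values are uncertain.

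Aged libraries were compared with adult libraries by limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(TPM + 1), for genes with a mean TPM of at least 1. A count model was not used because TPM are not counts. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The Benjamini-Hochberg adjusted p threshold was 0.05. Of 36 gene lists, 35 had at least 3 measured genes and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. The list of adrenal cortex markers had too few measured genes. Xist and Tsix, 2 members of the sex chromosome list, had no row. Each list was also scored per library as the mean of its genes' z-scores. Scores and library measures were compared by exact two-sided permutation over all 70 assignments of the libraries, for which the smallest possible p is 0.0286.

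The groups, the test, the lists and the rule for named genes were fixed before the data were examined. The rule named genes past the adjusted threshold. Where fewer than 10 passed, it added the 10 genes with the smallest unadjusted p, said not to pass. It also named genes of the renin-angiotensin system whatever their test, of which Agtr1a, Agtr1b, Ren1, Agt and Ace are given and the rest is not reported here, and up to 4 members with the smallest p of each list past its test or described. Members of the technical and other cell type lists were named where the level of such RNA was reported.

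Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, size factors, quantile normalization, removal of mitochondrial genes with rescaling, limma without trend, with robust estimation and with array weights, the replicate number as a block, each library left out, camera with an estimated correlation, and fry. After the data were seen, a split of the libraries by Y-linked transcripts at a summed 10 TPM, removal of each library's trend with transcript length, and addition of the nuclear copies were added. For the aged against adult comparison, data were simulated over 11796 genes, with 200 changed genes in each of 20 runs. The changed genes were drawn from those with a mean log2(TPM + 1) at least that of 5 TPM, and were shifted on that scale. Of the genes changed 2-fold 14.8% were recovered, and of those changed 4-fold 70.8%. Recovery of lower genes was not simulated. On average 4.1 unchanged genes were called per run, and 0 of the runs without changed genes made a call. A list shifted by 0.5 on the log2 scale was found in 20 of 20 runs, with genes simulated as independent.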

Results

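Kidney RNA was profiled in 8 mice carrying Hap-II of the human angiotensin receptor type 1 gene, which encodes the receptor through which angiotensin II raises blood pressure. All were on a western diet, and 4 adult animals were compared with 4 aged ones. The comparison asks how age changes the kidney transcriptome in this setting. Values are TPM, so read depth is unknown. Genes at or above 1 TPM numbered between 10663 and 12293 per library.

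Mitochondrially encoded transcripts, which encode subunits of the respiratory chain and ATP synthase, took a larger share of the aged libraries. The 13 protein-coding mitochondrial genes held 22.8% ± 3.02 of the TPM scale in adult kidneys and 35.9% ± 8.48 in aged kidneys (SD, n = 4 each). All 4 aged libraries lay above all 4 adult ones, a difference of 13.2 percentage points (SE 4.50, exact two-sided permutation p = 0.0286, the smallest possible, and 0.314 adjusted over 11 library measures). All 13 genes had positive log2 fold changes as deposited, with a median of 0.55, or 0.25 with quantile normalization. Among them mt-Co2, a cytochrome c oxidase subunit, averaged 13505 TPM in adult and 36375 TPM in aged kidneys (log2 fold change 1.32, SE 0.35), and mt-Atp8, an ATP synthase subunit, 20983 and 43464 TPM (1.04, SE 0.22). No member passed over all genes, while 4 passed when adjusted over the list alone, namely mt-Atp8, mt-Atp6, mt-Co2 and mt-Nd4. The list passed camera at the preset correlation (adjusted p = 9.24e-20), and had adjusted p = 0.618 with an estimated correlation. That estimate was 0.718, against the preset 0.01, so the smaller p treats the 13 genes as nearly independent. Adding 7 near-identical nuclear copies on chromosome 1 gave 32.5% ± 4.66 and 44.2% ± 7.06 (SD, n = 4 each), where the groups overlapped (exact permutation p = 0.0571). The copies alone held 9.73% ± 1.77 in adult and 8.29% ± 1.57 in aged kidneys (SD, n = 4 each). Mitochondrial genes can trade reads with these copies, which were not matched to single genes. Fold changes of single mitochondrial genes, mt-Co2 among them, are therefore uncertain.

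**Figure D1:**
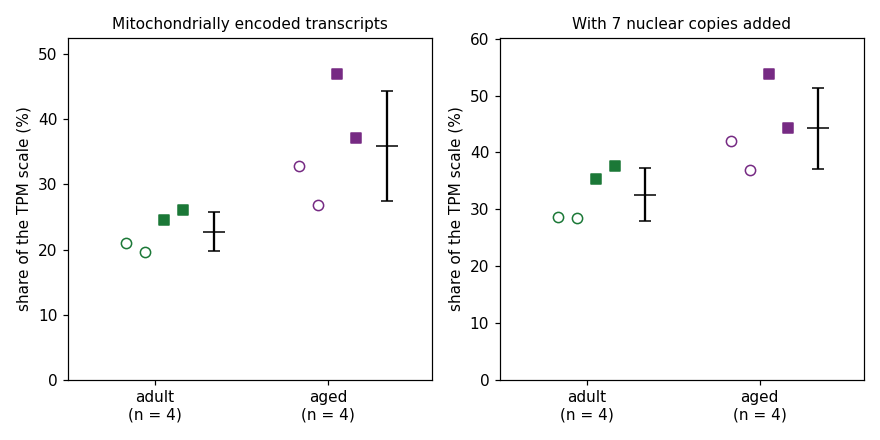
Share of the TPM scale (%) held by the 13 mitochondrially encoded protein-coding genes, left, and with 7 nuclear copies added, right. Each symbol is 1 library, open circles without and filled squares with Y-linked transcripts, and bars are mean ± SD (n = 4). On the left the adult libraries lie between 19.6% and 26.1% and the aged ones between 26.8% and 46.9%.

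No single gene passed the test between adult and aged kidneys. Of 11796 genes, 0 had a limma adjusted p under 0.05, and the lowest adjusted p was 1.00. An unadjusted p under 0.05 was found for 400 genes, 75 higher and 325 lower in aged kidneys, where 590 would be expected by chance. This test did not model the split by Y-linked transcripts described below, whose variation stayed within the groups. The 0 calls therefore do not show that no gene changed. The groups did not overlap for 290 genes (2.46%), against 2.86% by chance. The 10 genes with the smallest unadjusted p, none of which passed, were Gm15446, Sprr2a2, Ms4a4c, Gm9843 and Trbv13-2, lower in aged kidneys, and Gm12573, Gm15878, Rpl14-ps1, mt-Atp8 and Igkv10-94, higher. Gm15446, on chromosome 5 at 109923400 to 109943936, had 7.58 ± 2.02 TPM in adult and 1.57 ± 0.59 TPM in aged kidneys (SD, n = 4 each, log2 fold change −1.74, SE 0.30). Sprr2a2, a small proline-rich protein gene, had 14.6 ± 6.39 and 2.93 ± 1.41 TPM. Gm15878 was listed at 0 in every adult library. Gm12573, Gm15878, Rpl14-ps1 and Gm9843 are annotated as processed pseudogenes, whose values are uncertain. The median log2 fold change of all genes was −0.11 as deposited, with 65.0% of genes lower in aged kidneys. It was −0.01 with size factors (51.1% lower), 0.01 with quantile normalization (48.8% lower) and 0.15 with mitochondrial genes removed (30.4% lower), so list medians below are to be read against it.

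The renin-angiotensin genes did not pass the test as a group, and Ren1 had the largest difference of the genes of this system reported here. Ren1, which encodes renin, the enzyme that starts angiotensin formation, had 23.3 ± 10.6 TPM in adult and 7.32 ± 3.90 TPM in aged kidneys (SD, n = 4 each). Its log2 fold change was −1.54 (SE 0.39), with a limma adjusted p of 1.00 over all genes. It was the list's only member to pass when adjusted over the list alone (adjusted p = 0.0349), and 1 aged library at 13.1 TPM lay above the lowest adult one at 11.4 TPM. The mouse receptor gene Agtr1a had 13.3 ± 5.77 and 9.96 ± 3.23 TPM, and angiotensinogen (Agt) 12.1 ± 8.49 and 7.72 ± 5.26 TPM. Converting enzyme Ace had 31.4 ± 24.4 and 26.4 ± 17.7 TPM. Adult replicate 1 had the highest adult values of Ren1, Agt, Agtr1a and Ace. Without it the log2 fold change was −1.28 instead of −1.54 for Ren1 and −0.17 instead of −0.55 for Agt. It was −0.11 instead of −0.35 for Agtr1a and 0.26 instead of −0.19 for Ace. That of Ace was also positive without aged replicate 3 (0.12) and with mitochondrial genes removed (0.10). Agtr1b was listed at 0 in all adult libraries, at most 0.0997 TPM in aged ones, and was not tested. Of the 16 measured list members 10 had negative fold changes as deposited (median −0.14, camera adjusted p = 0.637). The median was 0.20 without adult replicate 1 and 0.10 without aged replicate 3. Without any other single library it lay between −0.48 (aged replicate 2 left out) and −0.07 (aged replicate 1 left out).

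**Figure D2:**
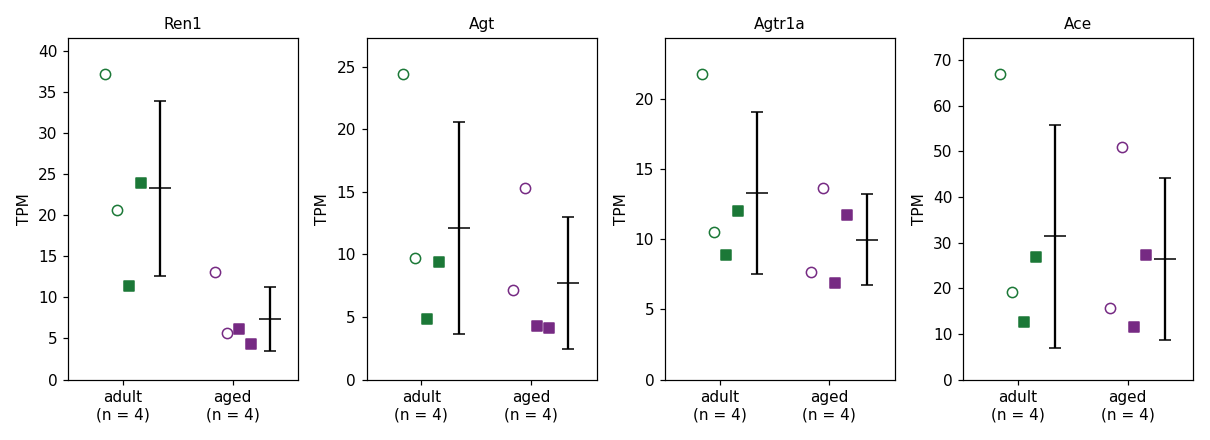
TPM of Ren1, Agt, Agtr1a and Ace in each library, open circles without and filled squares with Y-linked transcripts, with mean ± SD (n = 4 per group). Ren1 averages 23.3 TPM in adult and 7.32 TPM in aged kidneys, and every gene shows overlap between the groups.

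Nuclear genes of oxidative phosphorylation and antioxidant genes were lower in the aged kidneys at the preset correlation. Of 21 nuclear oxidative phosphorylation genes 20 had negative fold changes as deposited, with a median of −0.35 (camera adjusted p = 0.00195, and adjusted p = 0.911 with an estimated correlation). Cox5a and Cox4i1, subunits of cytochrome c oxidase, averaged 807 and 2509 TPM in adult and 537 and 1803 TPM in aged kidneys. The exception, Ndufa4, was listed at 0 in adult replicates 1 and 4. Of 20 antioxidant genes 18 had negative fold changes as deposited, with a median of −0.28 (adjusted p = 0.00465, and 0.911 with an estimated correlation). The peroxide-removing Prdx1 had 1046 ± 156 TPM in adult and 601 ± 67.0 TPM in aged kidneys (SD, n = 4 each, log2 fold change −0.79, SE 0.21), and glutathione peroxidase Gpx1 4913 and 3393 TPM. No member of either list passed over all genes or when adjusted over the list alone. The lists' scores per library had exact permutation p = 0.143 and 0.200 (adjusted p = 0.871 for both). With mitochondrial genes removed and TPM rescaled, neither list passed, with medians of −0.05 (adjusted p = 0.0528) and 0.02 (adjusted p = 0.0574). The median of all genes was 0.15 there, so both list medians still lay below it. With quantile normalization neither passed, with medians of −0.06 (camera adjusted p = 0.791) and −0.05 (0.669). With size factors the antioxidant list did not pass (median −0.16, adjusted p = 0.130), while the oxidative phosphorylation list did (median −0.23, adjusted p = 0.00960). The antioxidant list did not pass in the 4 libraries without Y-linked transcripts (adjusted p = 0.0739), and its median was −0.09 without aged replicate 3, −0.16 without adult replicate 1 and −0.46 without aged replicate 2.

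B and plasma cell genes, and immediate early with heat shock genes, were higher in the aged kidneys at the preset correlation. Of 9 measured B and plasma cell genes 8 had positive fold changes, with a median of 0.50 (adjusted p = 4.04e-05, and 0.911 with an estimated correlation). Igkc, the kappa light chain constant region, had 120 ± 67.4 and 285 ± 167 TPM, and Jchain, which joins antibody units, 17.4 ± 9.79 and 37.8 ± 17.6 TPM (SD, n = 4 each). The B and plasma cell median was 0.08 without aged replicate 4, 0.27 without adult replicate 4, 0.32 without adult replicate 2, 0.88 without adult replicate 1 and 1.01 without aged replicate 1. It was −0.00400 in the 4 libraries without and 1.18 in the 4 with Y-linked transcripts, and 0.25 with no filter, 0.30 with a pseudocount of 5, 0.79 with mitochondrial genes removed, 1.07 at a mean of at least 5 TPM and 1.16 with array weights. Of 10 immediate early and heat shock genes 9 had positive fold changes, with a median of 0.49 (adjusted p = 4.04e-05, and 0.911 with an estimated correlation). Egr1, a transcription factor induced within minutes of stimulation, had 7.20 ± 6.96 TPM in adult and 27.5 ± 27.9 TPM in aged kidneys (SD, n = 4 each). The aged libraries had 1.83, 8.63, 62.6 and 37.1 TPM and adult replicate 1 had 17.5 TPM, and the log2 fold change of Egr1 was −0.75 in the libraries without and 3.33 in those with Y-linked transcripts. In the 4 libraries without Y-linked transcripts neither list passed (adjusted p = 0.155 and 0.386), and the immediate early list had a median of −0.44 there, against 1.56 in the 4 with them. Without aged replicate 3 the immediate early list did not pass either (adjusted p = 0.268, median 0.27), and its median was 0.29 without adult replicate 3 and 0.83 without adult replicate 1. It was 0.25 with a pseudocount of 5 and 0.79 with mitochondrial genes removed. Scores per library had exact permutation p = 0.314 for B and plasma cell and 0.286 for immediate early genes (adjusted p = 0.871 for both).

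Endothelial genes were higher and red cell genes lower in the aged kidneys, again at the preset correlation. Of 11 endothelial genes 9 had positive fold changes, with a median of 0.12 (adjusted p = 0.0195, and 0.911 with an estimated correlation). Flt1 and Cdh5, a vascular growth factor receptor and an endothelial cadherin, averaged 6.60 and 5.77 TPM in adult and 10.1 and 7.72 TPM in aged kidneys. All 5 measured red cell genes had negative fold changes on the log scale, with a median of −1.08 (adjusted p = 0.0276, and 0.911 with an estimated correlation). The alpha globin genes Hba-a1 and Hba-a2, near-identical copies of each other, averaged 374 and 1047 TPM in adult and 178 and 544 TPM in aged kidneys. Summed hemoglobin averaged 5688 ± 3782 TPM in adult and 4602 ± 6707 TPM in aged kidneys (SD, n = 4 each, exact permutation p = 0.743). Aged replicate 1 had the highest of all libraries, 14650 TPM, and without it the red cell median was −2.04. The endothelial call was lost without adult replicate 2 (adjusted p = 0.0559), adult replicate 3 (0.215, median −0.11) or aged replicate 4 (0.0996, median 0.07), with the length trend removed (0.0791), no filter (0.0776) or array weights (0.278), and in the 4 libraries without Y-linked transcripts (0.225). Its median was 0.33 without adult replicate 1, 0.19 without adult replicate 4, 0.04 without aged replicate 2 and 0.30 without aged replicate 3. It was 0.23 with size factors, 0.26 with quantile normalization and 0.41 with mitochondrial genes removed. The red cell call was lost without adult replicate 2 (0.113), aged replicate 2 (0.481) or aged replicate 4 (0.185), and with size factors (0.0762), quantile normalization (0.103), no filter (0.115), a mean of at least 5 TPM (0.0579) or array weights (0.253). Scores per library had exact permutation p = 0.657 for endothelial and 0.229 for red cell genes (adjusted p = 0.871 for both).

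**Figure D3:**
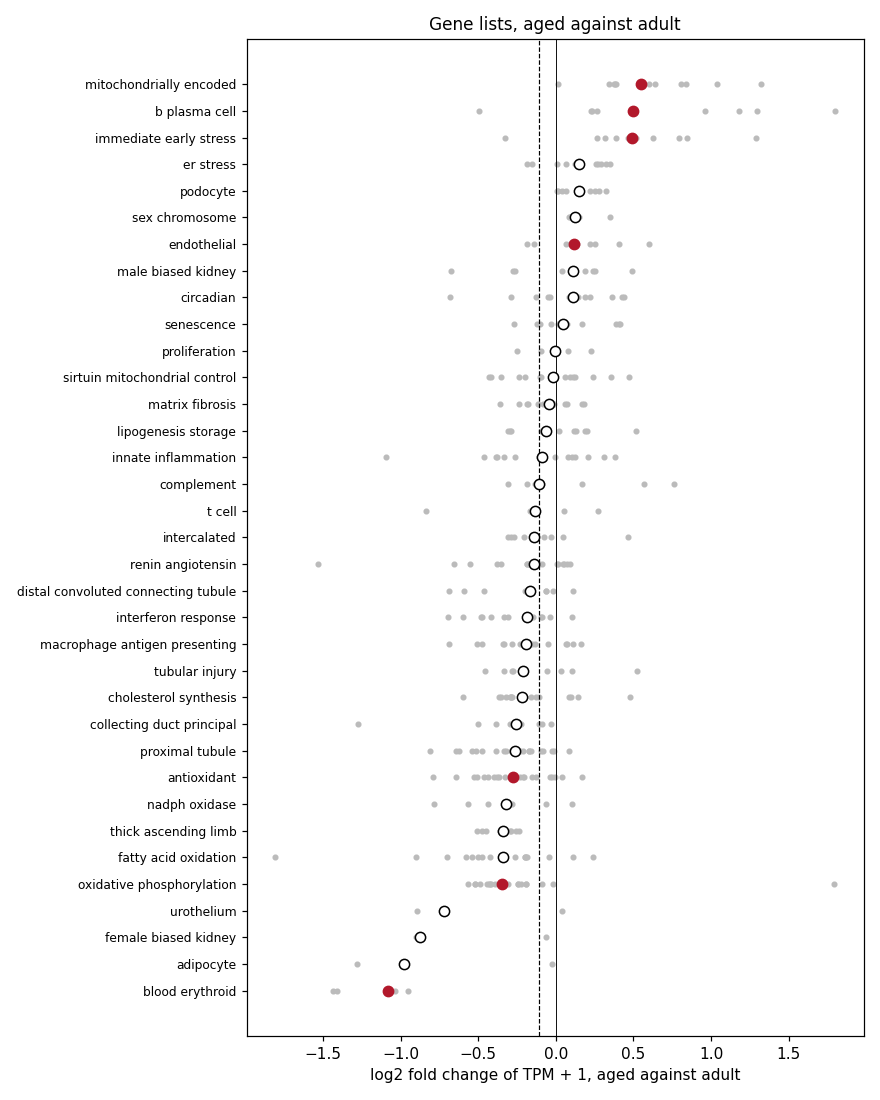
Log2 fold change of TPM + 1, aged against adult, for 35 gene lists. Grey points are single genes, large points list medians, filled for the 7 lists that passed camera at a preset correlation of 0.01, and the dashed line is the median of all genes at −0.11. With an estimated correlation 0 lists passed.

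The other 28 lists did not pass, although 13 of them did when some single library was left out, and the median of 20 changed sign in that way. Among kidney cell types the medians as deposited were −0.26 for proximal tubule (adjusted p = 0.188), −0.34 for thick ascending limb (0.289), −0.17 for distal convoluted and connecting tubule (0.744), −0.26 for principal cells (0.329), −0.14 for intercalated cells (0.772) and 0.15 for podocytes (0.0562). Proximal tubule Ass1, of arginine synthesis, averaged 1412 and 813 TPM in adult and aged kidneys. The proximal tubule median was 0.08 without adult replicate 1 and 0.03 without aged replicate 3. The list passed without adult replicate 2 (−0.32, camera adjusted p = 0.0163), adult replicate 3 (−0.53, 0.0336) or aged replicate 2 (−0.52, 0.00442). Fatty acid oxidation genes had a median of −0.34 (0.109), cholesterol synthesis −0.22 (0.744), lipogenesis and storage −0.06 (0.298), NADPH oxidase −0.32 (0.109) and sirtuins with mitochondrial regulators −0.02 (0.741). Cyba, the p22 subunit of NADPH oxidases, had 718 ± 39.2 TPM in adult and 421 ± 74.5 TPM in aged kidneys (SD, n = 4 each). It passed when adjusted over the list alone (adjusted p = 0.0226) and not over all genes. Matrix and fibrosis genes had a median of −0.05 (0.715), innate inflammation −0.09 (0.772), complement −0.11 (0.328), interferon response −0.19 (0.141), senescence 0.04 (0.124), tubular injury −0.21 (0.767), endoplasmic reticulum stress 0.15 (0.0562) and proliferation −0.01 (0.725). Markers of macrophages had a median of −0.19 (0.744), T cells −0.13 (0.715), adipocytes −0.98 (0.109) and urothelium −0.72 (0.0949), where Upk1a passed when adjusted over the list alone (adjusted p = 0.0221). The adipocyte median was −0.64 without adult replicate 1, and the list passed without adult replicate 4 (camera adjusted p = 0.0171) or aged replicate 1 (0.0281). The urothelium median was −0.37 without adult replicate 2, and the list passed without adult replicate 1 (0.0346), adult replicate 4 (0.0180) or aged replicate 3 (0.0156). The circadian list had 0.11 (0.160), the sex chromosome list 0.12 (0.337), the male-biased list 0.11 (0.714) and the female-biased list −0.88 (0.767). For the lipogenesis, matrix, proliferation, sirtuin and innate inflammation lists camera's direction was higher although the median was negative, and these medians lay above that of all genes. The tubular injury, intercalated and complement lists also had a higher direction, with medians below that of all genes and means of −0.11, −0.08 and 0.06. The male-biased list had a mean of −0.000823 against its positive median.

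Y-linked transcripts split the libraries in the same way within both age groups. The summed TPM of Ddx3y, Kdm5d, Eif2s3y and Uty was between 0.485 and 2.30 in replicates 1 and 2 of both groups, and between 34.7 and 50.6 in replicates 3 and 4. Kap, a kidney androgen-regulated protein, averaged 15198 TPM in the 4 libraries without and 62381 TPM in the 4 with Y-linked transcripts. With the class as a covariate 1464 genes differed between the classes by limma adjusted p, 133 higher and 1331 lower with Y-linked transcripts. With size factors 642 differed, 335 higher and 307 lower. The labels do not name this split, and it is balanced over age. With it as a covariate 0 genes passed for age, and 9 lists did at the preset correlation. For age, limma adjusted p was then 0.300 for Gm15446 and mt-Atp8, 0.375 for Ren1 and 0.374 for Prdx1. With the covariate and an estimated correlation 0 lists passed (lowest adjusted p = 0.237). The mitochondrial share was 20.3% and 29.8% in adult and aged libraries without, and 25.3% and 42.0% in those with Y-linked transcripts.

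**Figure D4:**
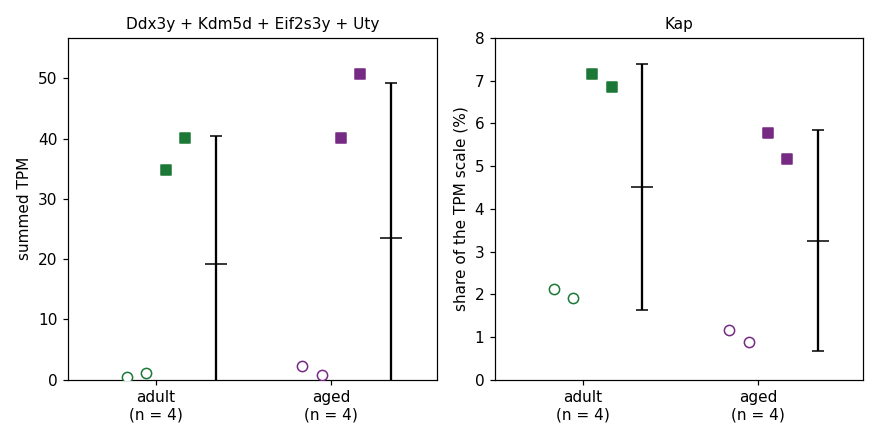
Summed TPM of 4 Y-linked genes, left, and share of the TPM scale (%) held by Kap, right, in each library, with mean ± SD (n = 4 per age group). Filled squares, the libraries with 34.7 TPM or more of the Y-linked genes, also have the higher Kap share in both age groups.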

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

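The tests on the mitochondrial share, on the Y-linked split and on the count of genes over other splits were chosen after the results were seen. The test of the length trend was added after the data were seen and before its own result, and the count of lists over other splits and the rescaling without mitochondrial genes were chosen before their results were seen.

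Chance could not be excluded for the count of lists in the age comparison. For the count of genes, all 35 of the 35 splits of the 8 libraries into groups of 4 gave at least the 0 of the age split, which a count of 0 fixes in advance, so it tests nothing. The highest other split gave 1385 genes, the one that follows the Y-linked transcripts, which points to a structure of the samples. The age split gave 7 lists at the preset correlation, and 28 of the 35 splits gave as many or more, up to 17. The list calls in the age comparison are therefore no more numerous than those between arbitrary groups of 4 libraries.

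The larger mitochondrial share in aged libraries was weighed against 3 explanations. Reads traded with nuclear copies on chromosome 1 would leave under 6.58 percentage points of difference in the joint share, but it kept 11.7 (SE 4.23). That is above the bound by less than 2 standard errors, and the groups overlapped in the joint share. Within each class of Y-linked transcripts they did not overlap. Without these transcripts the joint share was 28.4% and 28.6% in adult and 36.8% and 42.0% in aged libraries. With them it was 35.4% and 37.5% in adult and 44.3% and 53.7% in aged libraries. The copies alone went from 9.73% to 8.29%. These values argue against trading as the whole of the difference, while a part is not excluded. Unequal sexes are argued against by the classes of Y-linked transcripts, which are balanced over age, as far as these classes mark sex. That balance settles it whatever the gap within a class. The smallest gap between adult and aged libraries within a class was 5.84 points. More proximal tubule stays open: the mitochondrial list's mean change exceeded that of the proximal tubule list by 0.90, less than 2 standard errors (SE 0.67), a bound that a wide error alone can meet, and although the proximal tubule list's mean was −0.30, its median was 0.08 without adult replicate 1. Age itself, RNA quality and tissue handling also stay open and were not tested. Fold changes varied with transcript length too (rho 0.227 across genes), while the immediate early genes had a median of 0.49 in all libraries but −0.44 in the 4 without Y-linked transcripts, where the mitochondrial share was still higher in aged kidneys (20.3% and 29.8%).

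For the lower nuclear oxidative phosphorylation and antioxidant genes, 2 technical explanations were weighed. If the larger mitochondrial share made the call on oxidative phosphorylation, that list should not pass after rescaling without mitochondrial genes. It did not (camera adjusted p = 0.0528), nor did the antioxidant list (0.0574). The oxidative phosphorylation median went from −0.35 (SD of members 0.49) to −0.05 (0.52). Relative to all genes it went only from −0.24 to −0.20, so the call ended narrowly and a gap remained. With size factors this list still passed (median −0.23, adjusted p = 0.00960), so the rescaling does not settle the question. After each library's length trend was removed, both lists still passed camera at the preset correlation (adjusted p = 0.0233 and 0.0148). Arbitrary splits of the libraries also gave list calls at this correlation, so the calls alone decide little. Relative to all genes the oxidative phosphorylation median went from −0.24 to −0.18 and the antioxidant median from −0.17 to −0.20. Gaps thus remained, so poorer recovery of short transcripts, by the lengths used, did not account for all of them. Neither list passed with an estimated correlation, so chance also stays open.

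The split by Y-linked transcripts is a pattern that animals of both sexes in each age group may explain. All 12 of the 12 genes fixed beforehand as male-biased or female-biased separated the classes in the named direction. After size factors 12 of the 12 still differed by limma adjusted p, so library-wide scaling does not account for these genes. Most of their differences were far larger than the spread of size factors, 0.68 to 1.48, so this outcome was nearly fixed in advance. Scaling did bear on the wider split. As deposited 1464 genes differed, 1331 of them lower with Y-linked transcripts, and with size factors 642 differed, 307 of them lower. The labels give no sex, so animals of both sexes remain a hypothesis.

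Some values stood far from the other 3 libraries of their group. This happened in 17 of 277 groups of 4 values tested, where chance gives about 13.9 (1 in 20). Aged replicate 1 was high for summed hemoglobin (14650 TPM, against at most 1710 in the others), the red cell score (1.26), Hba-a2 (1693 TPM), Hba-a1 (548.8 TPM), Hbb-bt (1379 TPM), Alas2 (11.01 TPM), C4b (8.44 TPM), Lyz2 (215 TPM), Dcn (16.0 TPM) and Col3a1 (8.22 TPM). Adult replicate 3 was low for the interferon score (−1.23) and high for Igkv10-94 (1.14 TPM). Aged replicate 3 was low for the senescence score (−0.416), aged replicate 4 low for Ms4a4c (0.554 TPM), and aged replicate 2 high for Ddit3 (30.5 TPM). Adult replicate 2 was high for Sirt3 (96.6 TPM) and Upk1a (3.08 TPM).

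The age difference itself differed between the libraries with and without Y-linked transcripts for 4 genes, by limma's interaction term. The interaction, as log2 change with minus without, was 6.17 for Gm4737 (adjusted p = 0.00269), −4.37 for Gm28438 (0.00911), −3.70 for Gm10925 (0.00956) and −5.06 for Gm12918 (0.0196). Gm28438 and Gm10925 are nuclear copies of mitochondrial transcripts, Gm12918 is a processed pseudogene, and values of such genes are uncertain. Without Y-linked transcripts, Gm4737 had 122 and 134 TPM in the adult libraries and was listed at 0 in the aged ones. Each age group has only 2 libraries per class, so all 4 interactions rest on few values.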

How the results depend on the processing

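The splits by Y-linked transcripts, the length trend and the added nuclear copies were chosen after seeing the data. TPM hold no depth, so what depth limits is unknown. The count of 0 genes (limma, 400 at an unadjusted p under 0.05) became 1 with array weights (Gm15446), 3 in the 4 libraries without and 16 in the 4 with Y-linked transcripts, and ranged from 0 to 2 with each library left out. It was 1 without adult replicate 3 (Apoo-ps) and 2 without aged replicate 1 (Gm12396 and Gm5931). The count of 7 lists became 0 with an estimated correlation, 0 with fry, 0 with the Y-linked class as covariate and an estimated correlation, and 14 in the 4 libraries with Y-linked transcripts. It ranged from 5 to 14 with each library left out, with 12 without adult replicate 3, 14 without adult replicate 4, 12 without aged replicate 1 and 11 without aged replicate 2. The causes were not tested. Among single lists, the immediate early median was −0.44 in the 4 libraries without and the cholesterol synthesis median 0.14 in the 4 with Y-linked transcripts. The mitochondrial share difference kept its direction, from 9.48 to 16.2 points with each library left out. Of 96 named genes 74 kept their sign in each setting that gave them a value. With the replicate block 0 genes and 11 lists passed. Same-numbered libraries' deviations correlated at 0.04, 0.18, 0.49 and 0.42, not all above 0.1, and 4 of 8 libraries correlated best with their own number, so the numbers were not taken to pair the animals.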

Other observations

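The immunoglobulin test was chosen after the result was seen. The table holds 317 immunoglobulin genes, of which 76 were abundant enough to be tested. Of these, 71 had positive fold changes, and all 15 with an unadjusted limma p under 0.05 were higher. The summed TPM of all 317 was 332 ± 202 in adult and 763 ± 455 in aged kidneys (SD, n = 4 each, exact permutation p = 0.0857), and the groups overlapped. Aged replicate 4 alone had 1419 TPM, and without it the difference was 212 TPM instead of 431 TPM. A hypothesis is that aged kidneys may hold more B cell or plasma cell RNA. It stays open, because the 4 other B and plasma cell markers measured had a median log2 fold change of 0.23, from 1.18 for Jchain to −0.50 for Cd79b.

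In the 4 libraries with Y-linked transcripts 16 genes passed between adult and aged kidneys by limma. Egr1 averaged 4.05 TPM in adult and 49.8 TPM in aged libraries there. Whether this differs from the libraries without Y-linked transcripts was tested by the interaction, which Egr1 did not pass. Egr1 was singled out here after its values were seen, and each age group there has 2 libraries.

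Fold changes varied with transcript length across genes (Spearman's rho 0.227 over 11734 genes, which are not independent). The median log2 fold change as deposited was −0.17 for genes with a median annotated transcript length of 500 to 1000 bases. It was 0.06 for genes where that length was over 4000 bases.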
